A study of Mus musculus with 2 samples.

How the data were processed

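Total RNA-seq libraries of ES-E14 mouse embryonic stem cells were used, 2 libraries of 1 group; the labels give replicate numbers 1 and 2 and cite 1 source sample for both. The label's size range is 300 to 350, with no unit. Per the deposited text file, reads were placed on mm10 with the M4 annotation, and quantified per library from transcriptome alignments; the aligner and quantifier are not given in the sources used here. The deposited tables give, per gene and transcript and per the file headers, an expected count (fractional where reads are shared), TPM over all rows of the table, FPKM, and an effective length. They also give posterior mean TPM and interval bounds, used here as the authors' signal values, whose level is not given in the sources used here. The transcript tables give the deposited percent of each gene's output by transcript. The expected counts were rounded only for the count statistics.

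Gene symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, the same assembly as mm10. Of 43346 genes, 42462 matched; the 884 others held 6.79% and 9.11% of counts. The 26248 rows named by a number alone and 97 spike-in rows were left out of every statistic. Near-identical copies and overlapping genes share reads, so their values are uncertain.

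Depth was 43163300 and 45573500 expected counts on genes. The Wilson interval covers counting error only, and the bootstrap interval the spread between members of a list only. Detection was TPM of 1 or more in both libraries. Log values are log2(TPM + 1), so differences of low genes are understated. The lists, the rule for named genes and the tests were fixed before the data were examined: 31 gene lists, of which each list's median was set against 10000 random lists, and 11 comparisons between lists by two-sided permutation tests over genes (100000 resamples, difference of medians, shared members left out) with Benjamini-Hochberg adjustment. Exact tests between 2 and 2 samples cannot go below p = 0.333, and here 1 library stood on each side, so no p was computed between libraries. For differences between libraries, random lists were matched on mean expression (100 nearest genes). Matching on GC content of the most abundant transcript as well (the 50 nearest in GC of the 500 nearest in expression) was added after seeing the data, as were 6 further lists. With 37 lists, 1.85 would lie outside the 95% range by chance if the members of a list varied independently. Whether they do was not tested, and 6 of the lists were chosen after seeing the data, so this number is a rough guide.

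The rule named, for general, naive and formative lists, the 8 highest members and those under 1 TPM; for each other list the 3 highest and the lowest; the 15 highest protein-coding and 10 highest other genes; the 10 highest and 10 lowest differences among genes with a symbol and an expected count of 50 or more in a library; the 2 highest transcripts of chosen genes; and fixed pluripotency, methylation and sex-linked genes. Other genes named, including further members of the imprinted, Nodal, glycolysis and endoderm lists, were chosen after their values were seen. Zscan4a, Snhg1, Dancr and Peg13 had no match and are not reported here. For the closing tests on list percentiles, a verdict needed the same side of the limit under the main setting and all 6 alternatives; this rule was set after the results were seen. The median of the imprinted list minus that of protein-coding genes was given a 95% bootstrap interval over members under 3 scalings (10000 resamples), and its number of members 2-fold apart was set against 10000 random lists matched on mean expression.

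The dispersion used edgeR 4.0.16 with TMM factors, and DESeq2 1.42.0 size factors as an alternative, in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and BLAST 2.17.0. The statistics were tested on simulated data. In simulated libraries with a coefficient of variation of 0.30, the estimate was 0.312 over 17876 genes. Of 100 genes changed 2-fold, 42.0% passed the 2-fold limit, against 93.0% of 100 genes changed 4-fold; 2.41% of 9807 unchanged genes stood 2-fold higher and 3.17% lower. Of 300 unchanged lists, 4.67% lay outside the 95% range, and 5.33% when matched on GC as well. The simulated genes varied independently and without a trend by GC content, so these rates do not cover lists whose members move together. Of 300 null list pairs, 3.67% had a permutation p under 0.05.

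Alternatives were a TPM limit of 0.5 or 5, posterior mean TPM, FPKM, the lower interval bound, TPM rescaled to protein-coding genes without mitochondrial genes, a pseudocount of 0.1, count filters, TMM and DESeq2 scaling, means in place of medians, and each library alone.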

Results

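Total RNA was sequenced from ES-E14, an embryonic stem cell line derived from a male mouse embryo of the 129/Ola strain. The series held 1 group of 2 libraries, labelled biological replicates 1 and 2. The labels cite the same source sample for both, so the spread between them may be technical. The gene tables held 43163300 expected counts for replicate 1 and 45573500 for replicate 2, over 43346 genes. With 1 group the design allowed no comparison between conditions. The questions were which genes the cells expressed, whether the lists of cell states stood apart, and how far the libraries differed. Values are in TPM, the length-corrected share of all transcripts in a library, with the SD over n = 2 libraries. Replicate values are given in the order replicate 1, replicate 2.

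ES-E14 cells expressed 10739 genes at 1 TPM or more in both libraries, of which 9942 were protein-coding. These were 46.3% of the 21474 protein-coding genes in the table. The number depended on the scale: with TPM rescaled to protein-coding genes 12696 passed in both. By library the number was 11127 and 11552 genes. The most abundant protein-coding transcripts were mitochondrial mt-Co1 (2411.83 and 3220.1 TPM) and those of Lars2, Eef1a1 and Rplp1. The level of Lars2 is uncertain, since its counts differed widely between the libraries and ribosomal RNA reads on its model could not be excluded. Rplp1, a ribosomal stalk protein, stood at 1912.04 and 2216.33 TPM, and the elongation factor gene Eef1a1 at 1864.27 and 2324.86 TPM. Small structural RNAs were far more abundant: Rmrp, the RNA of an endoribonuclease, reached 81188 and 90739 TPM, and Rn7sk, which holds back transcription elongation, 70228 and 80072 TPM. The signal recognition particle RNAs Rn7s1 and Rn7s2 each stood at 67148 TPM in replicate 1, and at 86136 and 86980 TPM in replicate 2. These are near-identical copies, so their separate values are uncertain.

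Small RNAs took much of the TPM scale. Small nucleolar RNAs held 31.8% and 21.3% of all TPM but 1.16% and 0.606% of the expected counts, while protein-coding genes held 19.4% and 23.8% of TPM and 55.3% and 62.7% of the counts. Genes with an effective length under 5 bases took 21.6% and 15.5% of TPM. In all, 361 genes in replicate 1 and 315 in replicate 2 were listed at TPM 0 with an expected count above 0. The noncoding models Gm26917 and Gm42418 lie side by side on chromosome 17 from 39843013 to 39848788 and were treated here as models of ribosomal RNA. They took 26.4% and 16.4% of all counts, while mitochondrial ribosomal RNA took 0.229% and 0.515%. The share of ribosomal reads thus differed between the libraries, and the cause was not tested.

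All 15 general pluripotency genes were above 1 TPM in both libraries. Pou5f1 (ENSMUSG00000024406; chromosome 17, 35506018 to 35510772, mm10), which encodes the transcription factor OCT4, stood at 182 ± 27.3 TPM (SD, n = 2). Sox2 (ENSMUSG00000074637; chromosome 3, 34650405 to 34652461) stood at 35.7 ± 5.29 TPM, and Nanog (ENSMUSG00000012396; chromosome 6, 122707489 to 122714633) at 24.6 ± 10.4 TPM. The highest members were Dppa5a at 605 ± 11.6 TPM and Tdgf1, a Nodal co-receptor, at 258 ± 85.2 TPM. L1td1 followed at 56.6 ± 16.1 TPM, Fgf4 at 42.7 ± 12.4 TPM, Gdf3 at 36.7 ± 4.11 TPM and Utf1 at 33.7 ± 0.445 TPM. The median of the list lay at the 100th percentile of 10000 random lists of protein-coding genes.

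All 13 naive pluripotency genes were also above 1 TPM in both libraries, and the list lay at percentile 99.8. Zfp42, a zinc finger gene marking naive cells, stood at 96.5 ± 25.8 TPM, Fbxo15 at 54.8 ± 4.89 TPM and the nuclear receptor gene Esrrb at 31.1 ± 2.57 TPM. Klf4 stood at 16.7 ± 4.08 TPM, Nr0b1 at 14.8 ± 2.96 TPM, Tcl1 at 9.57 ± 0.12 TPM and Tfcp2l1 at 8.21 ± 0.0849 TPM. Of 14 formative and primed genes, 9 were above 1 TPM in both libraries. Dnmt3b led this list at 33.3 ± 2.45 TPM, and Lin28b stood at 5.17 ± 0.354 TPM. Under 1 TPM in both libraries were Fgf5 (0.04 and 0.17 TPM), Nkx1-2 (0.11 and 0.19 TPM) and Sox3 (0.23 and 0.5 TPM).

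The naive list stood above the formative and primed list by 1.82 log2 units in the difference of medians (p = 0.0024, adjusted p = 0.0029, two-sided permutation test over genes). The difference was 1.93 in replicate 1 and 1.71 in replicate 2. General pluripotency genes stood above neuroectoderm genes by 4.92, mesoderm by 4.79, endoderm by 4.87, trophectoderm by 4.34 and feeder fibroblast genes by 3.77 log2 units. Adjusted p was 0.00013 for the first 3, 0.0009 for trophectoderm and 0.00057 for feeder fibroblasts (permutation test). Naive genes stood above the same lists by 3.21, 3.07, 3.16, 2.63 and 2.05 log2 units. Their adjusted p ranged from 0.00013 to 0.014 (permutation test). All 11 comparisons formed 1 family with Benjamini-Hochberg adjustment, and both libraries gave the same direction in each. The p-values treat genes as the units, which are not independent replicates, and describe these lists in these libraries.

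**Figure D1:**
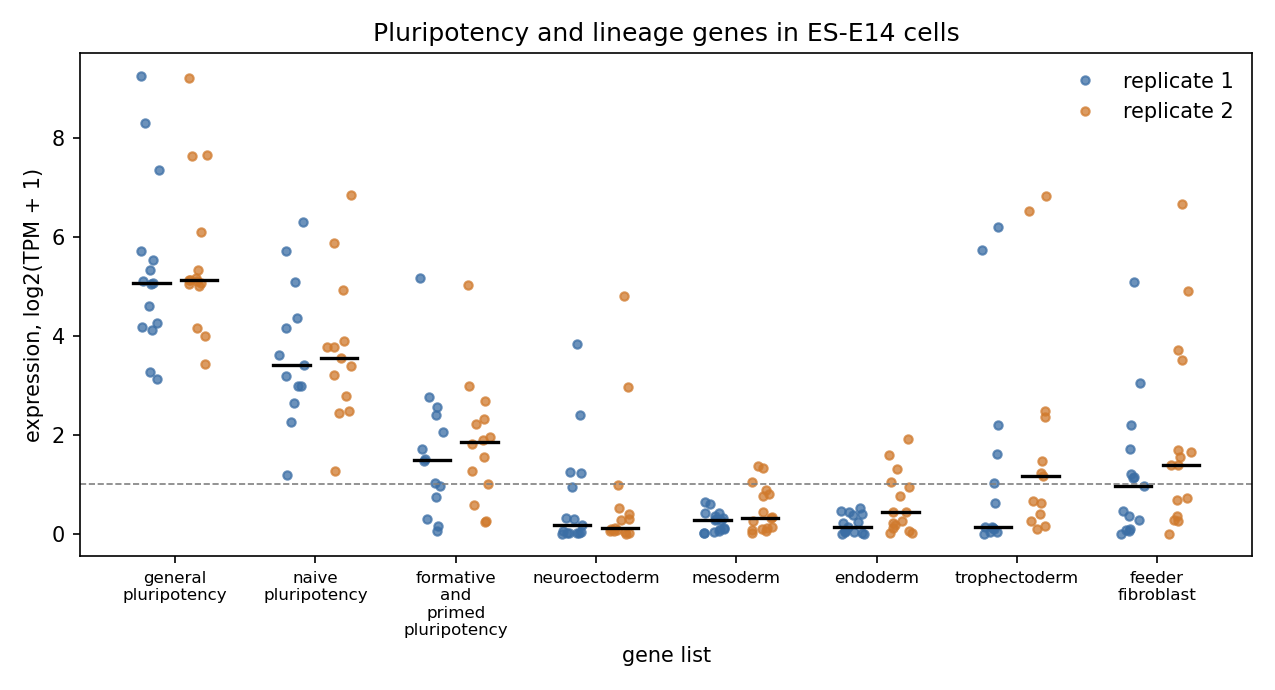
Expression of the genes of 8 lists in each library, as log2(TPM + 1) on the vertical axis. Each point is a gene in replicate 1 (blue) or replicate 2 (orange), black bars are medians and the dashed line marks 1 TPM; all 15 general and all 13 naive pluripotency genes lie above it.

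The number of germ layer genes above 1 TPM depended on the scale. Among random lists of protein-coding genes, neuroectoderm genes lay at percentile 13.4, mesoderm 18.9, endoderm 16.1, trophectoderm 43.9, germline 52.1, feeder fibroblast 68.2 and blood and endothelium 12.2, all inside the 95% range. None of 16 mesoderm genes and none of 15 endoderm genes was above 1 TPM in both libraries, against 2 of 15 for neuroectoderm, Tubb3 (13.28 and 27.12 TPM) and Nes (4.28 and 6.8 TPM). The mesoderm gene Twist1 stood at 0.51 and 1.59 TPM and the endoderm gene Sox17 at 0.35 and 1.47 TPM. With TPM rescaled to protein-coding genes 8 mesoderm, 5 endoderm and 5 neuroectoderm genes passed in both. Counting each library alone gave 3 mesoderm and 4 endoderm genes in replicate 2, and 4 neuroectoderm genes in replicate 1. Of 13 trophectoderm genes 5 passed, led by the keratin genes Krt8 at 93.1 ± 28.9 TPM and Krt18 at 71.8 ± 27.2 TPM. All 39 Hox genes, which pattern the body axis, were under 1 TPM in both libraries, while 2 passed in both with TPM rescaled to protein-coding genes. Of 14 germline genes 5 passed, or 11 when rescaled and 1 at 5 TPM, with Kit at 10.6 ± 2.93 TPM and Mael at 4.93 ± 1.44 TPM. Of 12 blood and endothelium genes 2 passed, Cd68 (6.14 and 5.3 TPM) and Tek (2.93 and 2.19 TPM), or 4 when rescaled.

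Of 13 genes of the 2-cell-like state 6 passed, or 12 when rescaled, led by Zscan4f at 47.4 ± 8.03 TPM. Zscan4c stood at 18.4 ± 2.74 TPM and Zscan4d at 12.4 ± 1.89 TPM. These are close paralogs, so reads could be split between them and single values are uncertain. Zscan4a was not analysed here. Of the 15 feeder fibroblast genes 7 passed, or 11 when rescaled, led by smooth muscle actin Acta2 (33.04 and 100.23 TPM) and the collagen genes Col1a1 (7.21 and 28.84 TPM) and Col1a2 (3.58 and 12.06 TPM), and Lum had 0 counts in both.

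Regulators of chromatin and signalling were broadly expressed. Of 12 genes for DNA methylation and its removal 11 passed: Zfp57, which protects imprints, stood at 84.9 ± 0.0707 TPM, Dnmt3l at 76.3 ± 18.8 TPM, Tet1 at 55.3 ± 13.9 TPM and Dnmt3a at 18.1 ± 0.573 TPM. All 12 Polycomb genes passed, led by Mtf2 at 45.0 ± 6.93 TPM, Cbx7 at 42.7 ± 3.04 TPM and Jarid2 at 41.3 ± 5.06 TPM. All 7 genes passed in each of the LIF, BMP, FGF-ERK and Nodal pathway lists, and 5 of 7 in the Wnt list. Lifr, the LIF receptor, stood at 19.9 ± 0.969 TPM, Etv5 at 30.0 ± 2.15 TPM and Ctnnb1 at 96.4 ± 13.3 TPM. All 17 G1-S genes passed, including Cdk4 at 120 ± 27.4 TPM, and so did all 16 glycolysis genes and all 12 nuclear respiratory chain genes. Gapdh stood at 530 ± 65.6 TPM and Cox4i1 at 489 ± 53.6 TPM. Of the 80 ribosomal protein genes 79 passed, and 60 of 64 histone genes.

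Xist, the RNA that silences an X chromosome, was at 0.12 and 0.52 TPM. The Y-linked genes Eif2s3y (10.07 and 15.12 TPM), Uty (6.61 and 7.71 TPM) and Ddx3y (5.24 and 11.72 TPM) were present, while Kdm5d, Zfy1, Zfy2 and Usp9y were below 1 TPM in at least 1 library. Of 16 immediate-early and stress genes 13 passed, with Hspa5 at 346 ± 5.48 TPM. All 10 long noncoding RNAs passed, with Malat1 at 405 ± 108 TPM. Of 12 small structural RNAs 8 passed, and of 37 mitochondrial genes 15. The other 22 mitochondrial genes, all for transfer RNAs, had no counts. Of 138 small nucleolar RNAs with symbols starting Snora or Snord 14 passed, against 40 of all 1484 genes of the small nucleolar RNA biotype. The imprinted list had 18 of 20 genes above 1 TPM, led by Rian at 215 ± 32.8 TPM and Meg3 at 51.4 ± 2.21 TPM.

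The levels of genes were closely related between the libraries. Across genes, Pearson's r of log2(TPM + 1) was 0.980 and Spearman's rho 0.945; for protein-coding genes they were 0.984 and 0.979. Genes are not independent replicates. Chi-square over its degrees of freedom was 305 over 19063 genes; it sets separate libraries against read sampling alone and tests no difference between cultures. The common biological coefficient of variation was 0.30.

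H19, an imprinted noncoding RNA (chromosome 7, 142575529 to 142578143), stood furthest above replicate 1 in replicate 2 among genes with an expected count of 50 or more in a library. It was at 2.96 TPM in replicate 1 and 136.7 TPM in replicate 2. The imprinted gene Nnat followed at 1.36 and 27.2 TPM, then Gm12671 at 0.11 and 9.94 TPM. Higher in replicate 2 were also Calcoco2 (4.48 and 36.97 TPM), the collagen genes Col5a2 (0.61 and 9.37 TPM) and Col3a1 (1.21 and 10.47 TPM), and the immunoglobulin genes Ighm (0.26 and 5.27 TPM), Ighv1-53 (0.26 and 5.08 TPM) and Igkc (0.39 and 5.37 TPM). Lars2, a mitochondrial leucyl-tRNA synthetase gene, had 332052 and 1850580 expected counts. Of the 10 lowest genes, 8 were small nucleolar RNAs listed at TPM 0 in replicate 2 with counts above 0, such as Gm22486 (1512 and 754 counts). Their TPM does not follow their counts: Gm25791 had 702 and 859 counts. The others were Gm28967 and mt-Co2 (616.78 and 18.56 TPM). Counts of mt-Co2 summed with its near-identical nuclear copy Gm28661 were 66558 and 77166. With the ranking limited to effective lengths of 100 bases or more, chosen after seeing the data, Fgf17 (15.36 and 3.09 TPM) and Notum (37.39 and 10.97 TPM) were among the lowest.

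Among 11436 genes with a mean of 1 TPM or more, 371 stood at least 2-fold higher in replicate 2 and 99 lower, with no test possible. In the simulated libraries, with a coefficient of variation of 0.30, 2.41% of 9807 unchanged genes stood 2-fold higher and 3.17% lower. Genes counted here therefore need not differ beyond the spread between libraries. The median protein-coding gene was 0.23 log2 units higher in replicate 2, so these counts depend on the scale. With TMM-scaled counts the split was 201 higher and 321 lower (38.5% higher against 78.9%), and with DESeq2 size factors 221 and 288. The difference also followed GC content: the median fell over GC deciles of protein-coding genes, from 0.40 in the lowest to -0.00394 in the highest.

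**Figure D2:**
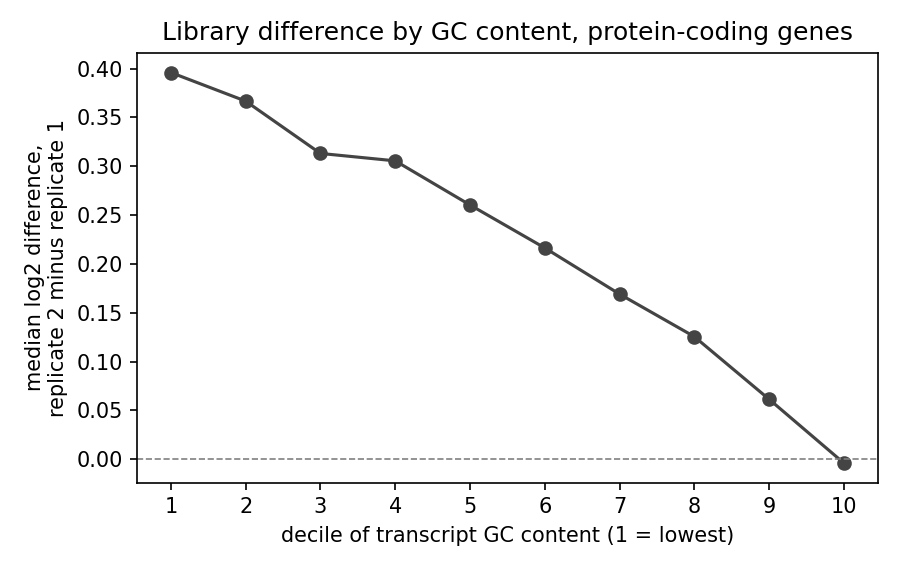
Median log2 difference (replicate 2 minus replicate 1) of protein-coding genes with a mean of 1 TPM or more, by decile of the GC content of the most abundant transcript. The median is 0.40 in decile 1 and -0.00394 in decile 10.

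Relative to random lists matched on mean expression, 7 of the 31 planned lists reached the upper 2.5% and 2 the lower 2.5%. Matching on GC content as well, chosen after seeing the data, put 8 in the upper 2.5%, with mesoderm genes added. The imprinted list had a median difference of 0.61 (percentile 99.99; 15 of 20 members higher, and 13 of 20 with TMM factors), with Peg3 (5.4 and 19.3 TPM), Peg10 (22.35 and 69.47 TPM), Mest (21.41 and 56.13 TPM) and Impact (8.41 and 30.25 TPM) higher, and Grb10 (18.68 and 7.86 TPM) and Phlda2 (52.17 and 25.77 TPM) lower. The feeder fibroblast list had a median of 0.44 (percentile 99.96; 13 of 15 higher), and 0.81 with TMM factors. Trophectoderm genes stood at 0.52 (percentile 100; 13 of 13 higher) and endoderm genes at 0.23 (percentile 99.98; 15 of 15 higher), or 0.64 when rescaled, such as Dab2 (0.43 and 2.77 TPM). Hox genes stood at 0.13 (percentile 100; 36 of 39 higher), or 0.29 with TMM factors. Histone genes stood at 0.54 (percentile 100; 52 of 64 higher), or at 0.24 with 39 of 64 higher with TMM factors.

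Nodal pathway genes stood lower in replicate 2, with a median of -0.48 (percentile 0.01; 1 of 7 higher), and -0.79 with TMM factors. Lefty1 stood at 137.59 and 65.5 TPM, Lefty2 at 42.71 and 16.06 TPM and Nodal at 53.19 and 37.86 TPM. Glycolysis genes had a median of 0.02 (percentile 1.31), which was -0.25 with TMM factors, with the glucose transporter genes Slc2a1 (329.01 and 146.65 TPM) and Slc2a3 (398.88 and 222.1 TPM) lower; matched on GC content the percentile was 2.56, inside the range. Sex-linked genes had a median of 0.44 (percentile 99.71), but lay inside the range when rescaled (median 0.29, percentile 96.8) and with a pseudocount of 0.1 (percentile 96.1). Mesoderm genes had a percentile of 94.9, and 98.95 matched on GC content; long noncoding RNAs had 3.76 and 0.54. The general, naive and formative lists lay at percentiles 49.9, 6.93 and 33.1.

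**Figure D3:**
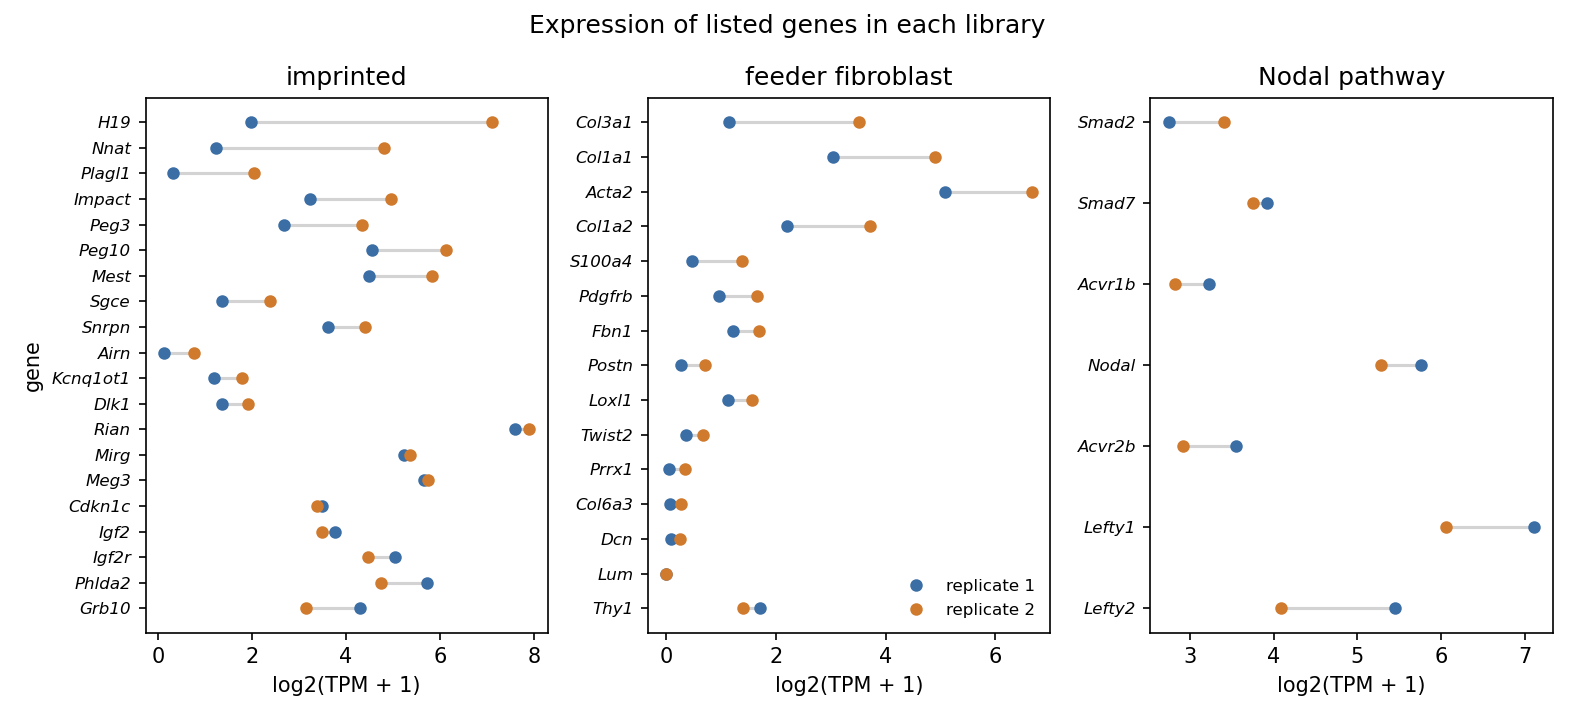
Expression of imprinted, feeder fibroblast and Nodal pathway genes in replicate 1 (blue) and replicate 2 (orange), as log2(TPM + 1) on the horizontal axis, 1 gene per line. H19 and Col3a1 lie at the top of their panels and Lefty2 at the bottom of its panel.

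For genes with several transcripts and at least 10 TPM in both libraries, the most abundant transcript was the same in 2179 of 2452 genes, 88.9% (95% Wilson interval 87.6 to 90.1%, counting error only). Pou5f1-201 took 97.7 ± 0.672% of Pou5f1 output (SD, n = 2). Dnmt3a-205, with 18 exons, took 71.7 ± 0.707% of Dnmt3a output and Dnmt3a-218, with 23 exons, 8.43 ± 0.728%. Nanog-201 took 77.2 ± 11.2%. The leading transcript changed for Esrrb, where Esrrb-206 took 48.3% and 39.3% and Esrrb-203 40.8% and 47.4%. It also changed for Dnmt3b, where Dnmt3b-207 took 32.5% and 25.0% and Dnmt3b-208 14.6% and 37.6%. Between the 2 highest transcripts of Tet1 the order changed as well. Tet1-201 took 29.4% and 32.1% of Tet1 output, and the other took 35.7% and 22.6%.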

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

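The tests by GC content, all 3 tests by scaling, and that on silenced germline genes were chosen after the imprinted result was seen, as was the rule that a verdict needs the same side of the limit under all 6 alternatives. The second lists, the B cell list and the tRNA synthetase list were themselves added after seeing the data. A limit called set beforehand was written before the values of such a list, not before the data were seen. The design has 1 group and names no biological difference between the libraries, so no biological explanation given by the design was tested. Rows named by a number alone, used in no comparison, held 15 expected counts in replicate 2, above the limit of 3 that a count of 0 allows. They held 1 in replicate 1.

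Imprinted genes stood apart between the libraries, with H19 at 2.96 and 136.7 TPM, and GC content did not account for it: the list stayed at percentile 99.98 among lists matched on GC content. Scaling as the whole cause was argued against by members that moved in both directions. With TMM factors 9 of 20 stood 2-fold apart, 7 higher and 2 lower (at most 5 in random lists, percentile 100). With DESeq2 size factors the number was 9, and when rescaled 11. The median over protein-coding genes, 0.60, could not decide, with a 95% bootstrap interval of -0.22 to 1.39. The interval reached below 0 under the other scalings too, which was the result written for scaling as a cause. The list's own percentile of 100 is no evidence, since a factor moves matched lists alike. The percentile of the number 2-fold apart also used lists that the factor moves. The argument against scaling therefore rests on members that moved in both directions. All these tests used the differences in which the pattern was first seen. Loss of methylation at imprinting control regions was left open: a second list of paternally expressed genes lay at percentile 89.2, under the limit set beforehand, but at or above that limit in 4 of 6 alternatives, up to 99.9, with 12 of 13 members higher and 4 under 1 TPM in both libraries, while a second list of maternally expressed genes, predicted not to stand higher, lay at percentile 4.28 (41.2 with TMM factors) with 10 of 22 higher. The planned imprinted list itself was not split by parental allele. More RNA of mesenchymal cells was left open. A second mesenchymal list lay at percentile 100 with 19 of 20 members higher. Its most abundant gene Fn1 was lower (154.13 and 122.22 TPM), Sparc was at 89.45 and 113.48 TPM, and 13 members were above 1 TPM in both libraries. The list was added after seeing the data, in which the planned feeder fibroblast list stood at percentile 99.96, so a high value was likely in advance. Endoderm (15 of 15) and trophectoderm genes (13 of 13) stood higher too, and no value ties the imprinted genes to mesenchymal RNA. Lower DNA methylation beyond imprinted genes also stays open. A second list of silenced germline genes lay at percentile 99.99, with 14 of 14 members higher (12 of 14 with TMM factors). The planned germline list lay at 64.5, with 9 of 14 higher and 7 of 14 with TMM factors. That planned list was not chosen for silencing by DNA methylation, so its percentile cannot decide this question.

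Immunoglobulin transcripts stood higher in replicate 2, with Ighm at 28 and 541 counts. RNA of B cells could not be decided: a list of 24 B cell genes lay at percentile 92.0, under the limit set beforehand, but at or above that limit in 4 of 6 alternatives, up to 99.96. In replicate 2, 19 of the 24 were higher, or 17 with TMM factors. Of these genes 18 lay under 1 TPM in both libraries and 4 were above it in both. Members moved apart, with Cd79a at 29 and 30 counts and Cd79b at 67 and 66 counts, against Ms4a1 at 5 and 31 counts and Jchain at 8 and 45 counts. The most abundant members were Laptm5 (18.81 and 10.47 TPM) and Cd37 (7.24 and 11.77 TPM).

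Counts of Lars2 differed 5.57-fold between the libraries. Higher expression together with other tRNA synthetase genes was argued against: their median difference was 0.12 log2 units over 36 genes, ranging from -0.49 to 0.81. Ribosomal RNA reads placed on the Lars2 model could not be excluded. A search of 9 Lars2 transcripts against 5 ribosomal transcripts found a longest shared stretch of 0 bases, but the searched set held no 28S model.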

How the results depend on the processing

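The protein-coding restriction of r, effective-length ranking, rescaling in the library difference, GC matching and posterior means of single genes were chosen after seeing the data. All 66 alternative values of the list comparisons kept their direction and their side of the threshold, from 1.71 to 7.11 log2 units with adjusted p up to 0.016; with each library alone they are among these. Genes detected fell to 5615 at 5 TPM, and ranged from 11127 to 11552 with each library alone. Protein-coding genes detected rose from 9942 to 12696 when rescaled. Pearson's r was 0.982 with a pseudocount of 0.1, 0.969 with 10 counts in both libraries, 0.977 with posterior mean TPM and 0.984 for protein-coding genes. At 5 TPM the lists kept 1 formative, 1 neuroectoderm, 2 trophectoderm, 1 germline, 2 feeder fibroblast, 8 G1-S, 4 BMP, 1 Wnt, 5 immediate-early and stress and 1 blood and endothelium genes. At 0.5 TPM 2 mesoderm and 10 germline genes passed, and at FPKM 1 9 germline genes. Rescaling to protein-coding genes gave 12 genes for 2-cell-like, 5 for neuroectoderm, 8 for mesoderm, 5 for endoderm, 11 for germline, 11 for feeder fibroblasts, 4 for blood and endothelium and 2 for Hox genes; posterior mean TPM gave 4 for neuroectoderm. With each library alone the count ranged from 2 to 4 for neuroectoderm, from 0 to 3 for mesoderm and from 0 to 4 for endoderm. Genes 2-fold higher and lower in replicate 2 numbered 776 and 195 with a pseudocount of 0.1, 201 and 321 with TMM factors, and 221 and 288 with DESeq2 factors. At a mean of 5 TPM 219 stood higher, with effective lengths of 100 bases or more 65 stood lower, and for rescaled protein-coding nuclear genes 322 stood lower against 56. The scale itself moves these counts. The glycolysis percentile became 2.56 with GC matching, and the sex-linked one 96.1 with a pseudocount of 0.1 and 96.8 when rescaled; the cause was not tested. The same leading transcript was found in 85.9% of genes at 1 TPM or more. The library difference, agreement and leading transcript cannot be computed with 1 library left out. Of the named genes, 161 moved by less than 1 SD with posterior mean TPM and 18 by more. Outside the main calls, BMP genes reached percentile 98.5 with a pseudocount of 0.1 and when rescaled, ribosomal proteins 97.8 when rescaled, and with GC matching mesoderm 98.95 and long noncoding RNAs 0.54; the cause was not tested. No paired analysis was possible because there was 1 group. Which expression levels depth limits was not tested.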

Other observations

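The second list of maternally expressed genes and the genes named here other than Id1, Id3 and Bmp4 were chosen after the data were seen. The BMP target genes Id1 (14.33 and 28.23 TPM) and Id3 (15.23 and 29.19 TPM) were higher in replicate 2, while Bmp4 was at 13.56 and 5.62 TPM. The collagen IV genes Col4a1 (14.88 and 42.08 TPM) and Col4a2 (7.81 and 22.91 TPM), Vim (88.91 and 301.94 TPM) and Tagln (42.26 and 109.83 TPM) stood higher as well. Among other pathway lists, the percentile of the library difference was 92.1 for BMP, 89.2 for Wnt, 17.9 for LIF and 20.5 for FGF-ERK genes.

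Summed counts of lists with low levels differed in ratio between the libraries. Replicate 2 held 3.67 times the counts of replicate 1 for Hox genes, 4.59 times for endoderm, 2.23 times for mesoderm, 1.55 times for neuroectoderm, 1.04 times for B cell and 0.892 times for blood and endothelium genes. The 1659 olfactory and vomeronasal receptor genes summed to 552 and 605 counts, a ratio of 1.10. Of the second list of maternally expressed imprinted genes, Cd81 was at 195.27 and 94.51 TPM.

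A gene without a symbol in the annotation used here, ENSMUSG00000045999, held 1579600 and 3544850 expected counts.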
